A study of Mus musculus with 58 samples.

How the data were processed

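Bulk RNA sequencing of mouse prefrontal cortex was analysed, with 58 libraries from as many mice (strand-specific libraries from polyadenylated RNA, per the labels' protocols). The deposited table holds normalized counts for 18088 Ensembl genes, a signal in units of reads divided by a size factor of each library. Per the submitters' processing notes the authors used Salmon 0.11.2, R 3.6.0, DESeq2 1.19.11 and the mouse genome build GRCm38; which options were set is not given in the sources used here. Within each column the deposited values were whole multiples of a step between 0.788 and 1.30, so that 100% of values came out whole within 0.01 after division, and whole reads were recovered. In 11 columns the step lies so near 1 that this test alone does not tell reads from rounded values; their decimals match those of the other columns. Recovered totals, rounded, ran from 23270000 to 37800000 reads with a median of 27910000, and the normalized totals from 27350000 to 30930000. Division by size factors assumes that most genes do not change, so that a general shift in RNA content per cell would not be seen. Reads shared by near-identical genes are divided by the quantification itself, so values of pseudogenes, retroposed copies and their parents are uncertain.

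Gene symbols, positions and biotypes came from the GENCODE annotation of GRCm38, in which 18077 of the gene identifiers were found. Groups and replicate numbers came from the labels. Sex labels were checked against Xist and Ddx3y, and all 30 females and 28 males matched. Among all 1653 pairs of libraries none agreed within sampling noise (chi-square per degree of freedom of at least 3.15), so no library was counted as a repeat.

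Before the data were examined, the design named edgeR for counts and limma with trend for normalized values. The deposited values are normalized, so limma 3.58.1 with trend on log2(value + 1) was the test, with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 (Wald test) on the recovered reads as alternatives. Genes with a value of at least 10 in at least 4 libraries were kept, 17925 in all; 2 genes had 0 in every library. All 58 libraries entered one fit with 12 groups of genotype, drug and sex, which share one estimate of the spread. Each contrast weighed females and males equally. A gene passed with a Benjamini-Hochberg adjusted p under 0.05 within a comparison, two-sided. Values written with ± are log2 differences with their SE unless SD is named, and fold changes on the log2(value + 1) scale understate the change of low genes. The 9 main comparisons were the genotype effect under each drug arm, each drug effect in each genotype and the interactions of drug and genotype; sex interactions and effects within a sex came from the same fit.

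Genes were named by a rule fixed before the data were examined: Tanc2, the 10 genes with the smallest p in each direction of a drug effect or the genotype effect in vehicle among those that passed with a mean CPM of at least 1, the 3 smallest for other comparisons, the 3 smallest p where none passed, and up to 4 members of a list described. Unnamed gene models and predicted transcripts were passed over in naming, not in counting. Of 33 gene lists written beforehand (synaptic, signalling, stress and metabolic groups and markers of cell types and neighbouring tissue), 31 were tested with camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 31. Camera was repeated with a correlation estimated from the residuals, and fry was run beside it. The oxidative phosphorylation list takes in assembly factors of complex I besides subunits. Members were counted both with adjustment over all genes and over the list alone.

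Similarity of effects was measured as Pearson's r and covariance across genes, with 100 simulations of unchanged groups and with shared control libraries divided into separate sets. The alternatives fixed beforehand were DESeq2, a stricter filter, pseudocounts of 0.1 and 5, added quantile normalization, only the groups compared, 2 surrogate variables (sva 3.50.0), each sex alone, replicate numbers as a block, the list tests above and leaving out each library in turn. Others were chosen after seeing the data: edgeR, a term for presence of Gm10221 reads with sex additive, only libraries without those reads, a covariate from olfactory bulb markers, leaving out the library highest in those markers, and removal of trends on transcript length and GC content. Also chosen then were the lists with each library left out in turn and a search for 31-base sequences that the GENCODE transcripts of a gene share with those of another. The same holds for the pooled genotype effect over the 3 drug arms and the comparison of lithium with fluoxetine in females with Gm10221 reads. For each comparison 100 splits of its libraries into sets of the same sizes, the real one included, were refitted.

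The pipeline was tested on simulated counts for the fluoxetine effect in WT mice, drawn for the real genes with 17847 tested. Limma recovered 63 of 80 genes changed 1.25-fold (78.8%), 56 of 60 changed 1.5-fold (93.3%) and 60 of 60 changed 2-fold, with 14 false calls. The changed genes were drawn only from those above a minimum mean count, and each gene was simulated independently of the others. Recovery among scarcer genes, or with differences between libraries that many genes share, was not measured. No litter, cage or sequencing batch is named in the labels; 0 mice have a litter label, and neither could enter a fit.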

Results

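RNA was measured in the prefrontal cortex of 58 mice, each a library of its own. Tanc2 encodes a scaffold protein found at synapses, and the mice were labelled wild type (WT) or heterozygous (HT) for it. Females and males were included, and the drug was vehicle, fluoxetine (a serotonin reuptake inhibitor) or lithium (a mood stabiliser that inhibits GSK3 and inositol phosphatases). The 12 groups of genotype, drug and sex held 5 mice each, except WT vehicle males and HT lithium males with 4. Pups received the drug through the milk of treated dams from postnatal day 3 to day 24, and tissue was taken at day 25. Between 23270000 and 37800000 reads per library lay behind the values, with a median of 27910000. The labels name no litter, so the p-values treat mice as independent although a drug reached whole litters.

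Tanc2 was not lower in the mice labelled HT. Tanc2 (ENSMUSG00000053580, GRCm38 chromosome 11, 105589986 to 105929304) had means between 7348 normalized reads in WT fluoxetine females, with an SD of 523 (n = 5), and 8357 in HT vehicle males, with an SD of 342 (n = 5). Its log2 difference, HT-labelled minus WT-labelled, was 0.10 ± 0.04 (SE) under vehicle (limma adjusted p = 0.947), 0.10 ± 0.04 under fluoxetine (adjusted p = 0.745) and 0.09 ± 0.04 under lithium (adjusted p = 0.436). Over the 3 drug arms it was 0.10 ± 0.03 (adjusted p = 0.436), a comparison chosen after seeing the data. Tanc2 was named beforehand, and its unadjusted limma p was 0.0244, 0.0237 and 0.0462 in the 3 arms and 0.000316 over them. It thus lay slightly higher in HT-labelled mice in each arm, with mice treated as independent. The labels do not say which part of the gene is altered, and a value summed over the whole gene need not show a partial deletion. The value therefore does not check the genotype labels, and the groups are called HT-labelled and WT-labelled below.

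**Figure D1:**
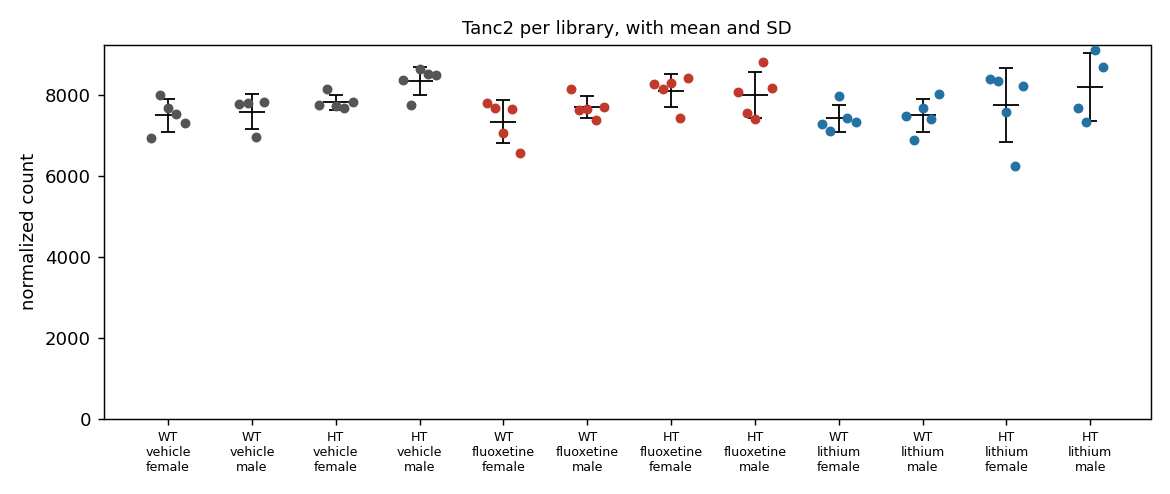
Normalized read count of Tanc2 (y axis) in each library, by genotype, drug and sex (x axis); points are libraries, and bars show the mean and SD of each group. The groups overlap, and the highest mean (8357) belongs to HT vehicle males.

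The first comparison asked what the Tanc2 genotype did in vehicle mice. No gene passed between 10 HT-labelled and 9 WT-labelled vehicle mice by limma, where 814 of 17925 genes had an unadjusted p under 0.05. DESeq2 called 3 genes and edgeR 0. The genes with the smallest p did not pass: Pla2g3, a secreted phospholipase, at 0.67 ± 0.15 (adjusted p = 0.586), Bmp1, a procollagen protease, at 0.25 ± 0.07, and Cbx7, a Polycomb subunit, at 0.14 ± 0.04. Cholesterol synthesis genes had a median of -0.11, with 25 of 30 members lower, and 11 lower when adjusted over the list alone. Markers of myelinating oligodendrocytes lay lower in 35 of 36 members (median -0.20), and interferon response genes lay higher in 30 of 31 (median 0.24). Immediate early genes, which neurons switch on after activity, lay higher in 34 of 41 (median 0.14). A single mouse, HT vehicle male 1, carried much of the interferon value: without it 24 of 31 members lay higher (median 0.087). Without WT vehicle male 3 the myelin median went to -0.300. Camera called these 4 lists with its preset correlation, but with an estimated correlation none was called, with adjusted p = 0.150 for cholesterol synthesis, adjusted p = 0.575 for the myelin list and adjusted p = 0.567 for each of the other 2.

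Camera called 6 more lists for genotype in vehicle, again with 0 genes passing. Markers of deep layer neurons lay lower in 19 of 25 members (median -0.12) and of striatal neurons in 20 of 24 (median -0.18), with adjusted p = 0.567 and adjusted p = 0.731 with an estimated correlation. Heat shock genes lay lower in 14 of 19 (median -0.096, with 3 lower when adjusted over the list alone), presynaptic genes in 47 of 60 (median -0.047) and those of the excitatory postsynapse in 47 of 65 (median -0.028), while cytosolic ribosome genes lay higher in 75 of 84 (median 0.039). With an estimated correlation these 4 had adjusted p = 0.364, adjusted p = 0.689, adjusted p = 0.80 and adjusted p = 0.795. Leaving out WT vehicle male 1 ended the striatal call (adjusted p = 0.0661, median -0.124), and without WT vehicle male 3 its median was -0.274. The heat shock median was -0.064 without HT vehicle female 1. The call of the excitatory postsynapse ended when any 1 of 7 libraries was left out, WT vehicle males 1 (adjusted p = 0.0881) and 2 (0.0530) and females 3 (0.0955) and 4 (0.0586) or HT vehicle male 2 (0.145) and females 3 (0.0860) and 4 (0.124), and its median was -0.045 without HT vehicle female 2 and -0.046 without WT vehicle male 3.

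A feature of the libraries runs alongside the drug groups and bears on every lithium value below. Gm10221, a processed pseudogene on chromosome 5, had reads in 27 libraries (mean 177 normalized reads, from 61.0 to 256) and 0 reads in the other 31. The 27 were all 19 lithium libraries, all 5 HT fluoxetine females and 3 of the 5 WT fluoxetine females. No vehicle library and no fluoxetine male had any. Libraries with these reads also had a mean of 52088 normalized reads for mt-Atp6, a mitochondrially coded ATP synthase subunit, against 23274 in the others, and 337 against 154 for Scand1. Among WT fluoxetine females alone, mt-Atp6 ran from 44646 to 65695 in the 3 libraries with Gm10221 reads and from 11019 to 23007 in the 2 without.

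**Figure D2:**
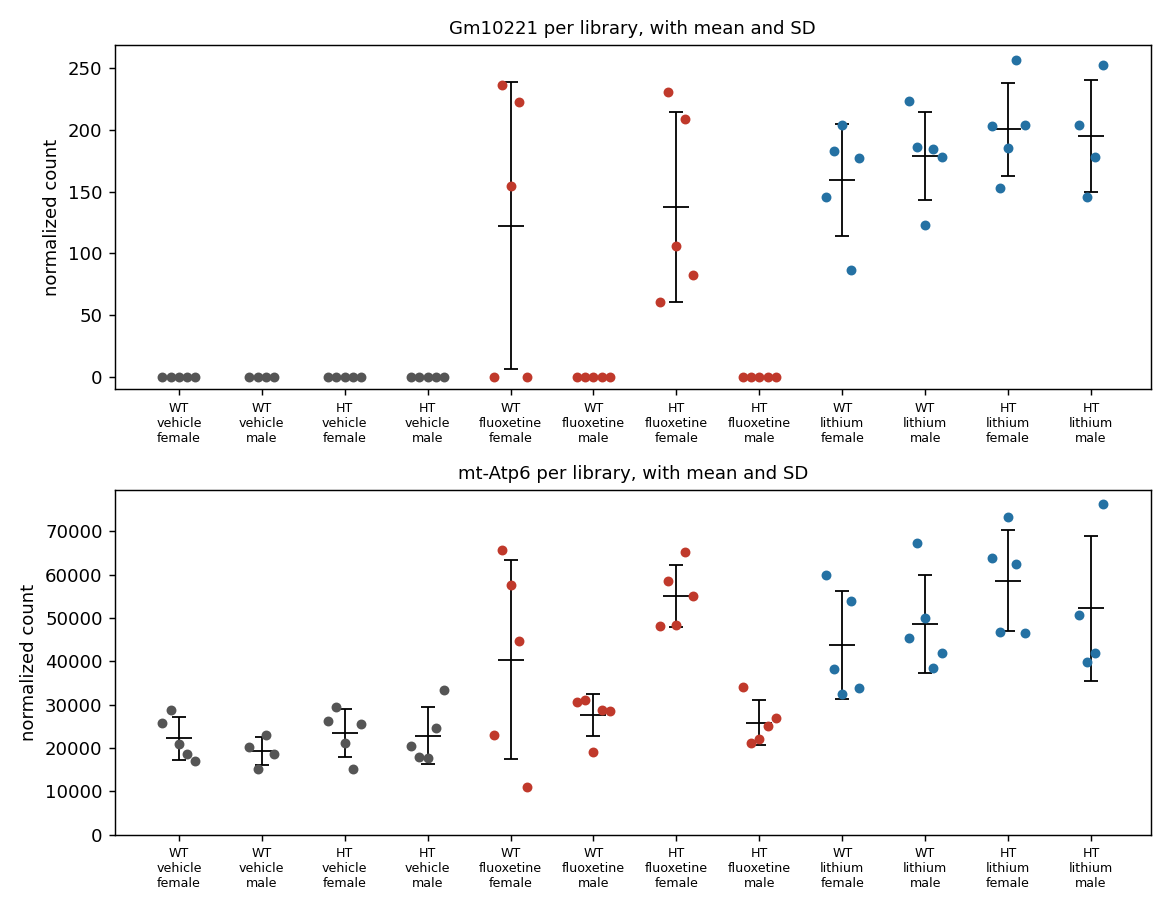
Normalized read counts of Gm10221 (upper panel) and mt-Atp6 (lower panel) in each library, by group (x axis); points are libraries, and bars show the mean and SD of each group. Gm10221 has reads in 27 libraries and none in 31, and mt-Atp6 averages 52088 in the former and 23274 in the latter.

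Fluoxetine in WT-labelled mice lowered immediate early genes and genes of cholesterol synthesis. Of 41 immediate early genes 14 fell and 0 rose, with 24 falling when adjusted over the list alone; the median log2 change was -0.33. Arc, an activity-regulated synaptic protein, fell by 1.40 ± 0.25 (limma adjusted p = 0.000432), from 3082 ± 1100 normalized reads (SD, n = 9) to 1156 ± 441 (n = 10), and was lower in 10 of 10 treated mice than the vehicle mean of their sex. Nr4a3, an activity-induced nuclear receptor, fell by 0.999 ± 0.15, and Gadd45b and Spry4 fell by 0.56 ± 0.10 and 0.38 ± 0.06. Of 30 cholesterol genes 15 fell and 0 rose, 24 of them when adjusted over the list alone, and the median was -0.20. Idi1, which makes the isoprenoid building block of sterols, fell by 0.40 ± 0.06 (adjusted p = 1.19e-05), from 2251 ± 157 to 1707 ± 161 normalized reads. Insig1, Stard4 and Cyp51 fell by 0.33 ± 0.05, 0.40 ± 0.07 and 0.31 ± 0.06. Both list scores were lower in 10 of 10 treated mice.

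Other genes that fell in these mice included Stk40 (-0.50 ± 0.05), a kinase-like protein, and Nab2 (-0.51 ± 0.06), a corepressor of EGR factors. The zinc-finger genes Zfp189 and Zfp366 fell by 0.67 ± 0.09 and 0.79 ± 0.10, and the transcription factor gene Klf10 by 0.97 ± 0.12. Per1, a clock gene, fell by 0.45 ± 0.06, Itpkc, an inositol phosphate kinase, by 0.51 ± 0.06, and Chrm4, a muscarinic receptor, by 0.57 ± 0.08. Phf13 completed the 10 with the smallest p among the lower genes (-0.44 ± 0.05). Among the genes that rose, Flrt3, an adhesion protein, stood first at 0.37 ± 0.06, with Ccdc141 at 0.45 ± 0.08 and Nrde2 at 0.31 ± 0.06. Sult1a1 (0.70 ± 0.13), Hif3a (0.78 ± 0.15), Mertk (0.31 ± 0.06) and Fkbp5 (0.57 ± 0.13) rose too. These 4 belong to the glucocorticoid response list, in which 4 of 22 genes rose and 3 fell, 7 and 4 when adjusted over the list alone, and camera did not call it (adjusted p = 0.0675). Smaller rises were those of Ppp1r10 (0.17 ± 0.03), Saal1 (0.25 ± 0.05) and Lcmt2 (0.37 ± 0.07), and the scarcely expressed Tceanc rose by 0.71 ± 0.14. In the unfolded protein response list Dnajb11 (0.13 ± 0.03) and Creld2 (0.26 ± 0.07) rose, 2 of 27, or 5 when adjusted over the list alone, and the call was lost with adjusted p = 0.513 with an estimated correlation.

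In all, 248 genes passed for fluoxetine in WT-labelled mice, 84 higher and 164 lower. Camera called 6 lists. The calls of immediate early genes (adjusted p = 3.91e-24) and cholesterol synthesis (adjusted p = 8.88e-37) held with an estimated correlation (adjusted p = 0.00490 and adjusted p = 0.00150). Besides the unfolded protein response, 3 lists of cell types lay lower: markers of myelinating oligodendrocytes (median -0.16, 0 of 36 passing), endothelial and mural markers (median -0.09, with Emcn at -0.37 ± 0.10 the 1 of 28 that fell) and red blood cell genes (median -0.34, 0 of 9 passing). Each had adjusted p = 0.986 with an estimated correlation. The myelin median ran from -0.261 without WT fluoxetine female 1 to -0.099 without WT fluoxetine female 4 (-0.259 and -0.109 without WT vehicle males 3 and 2). The endothelial call ended without WT vehicle female 1 or male 3 or WT fluoxetine female 1 or male 2, and the red blood cell call without WT vehicle male 2 or WT fluoxetine female 3 or male 5. Among the 31 libraries without Gm10221 reads 146 genes passed, 108 of them shared with the 248, and with those reads as a term of the fit 129 passed, 124 of them shared. Without WT vehicle male 1 the count was 159, and without WT fluoxetine female 5 it was 373; the libraries of the 4 groups compared gave 158 on their own.

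**Figure D3:**
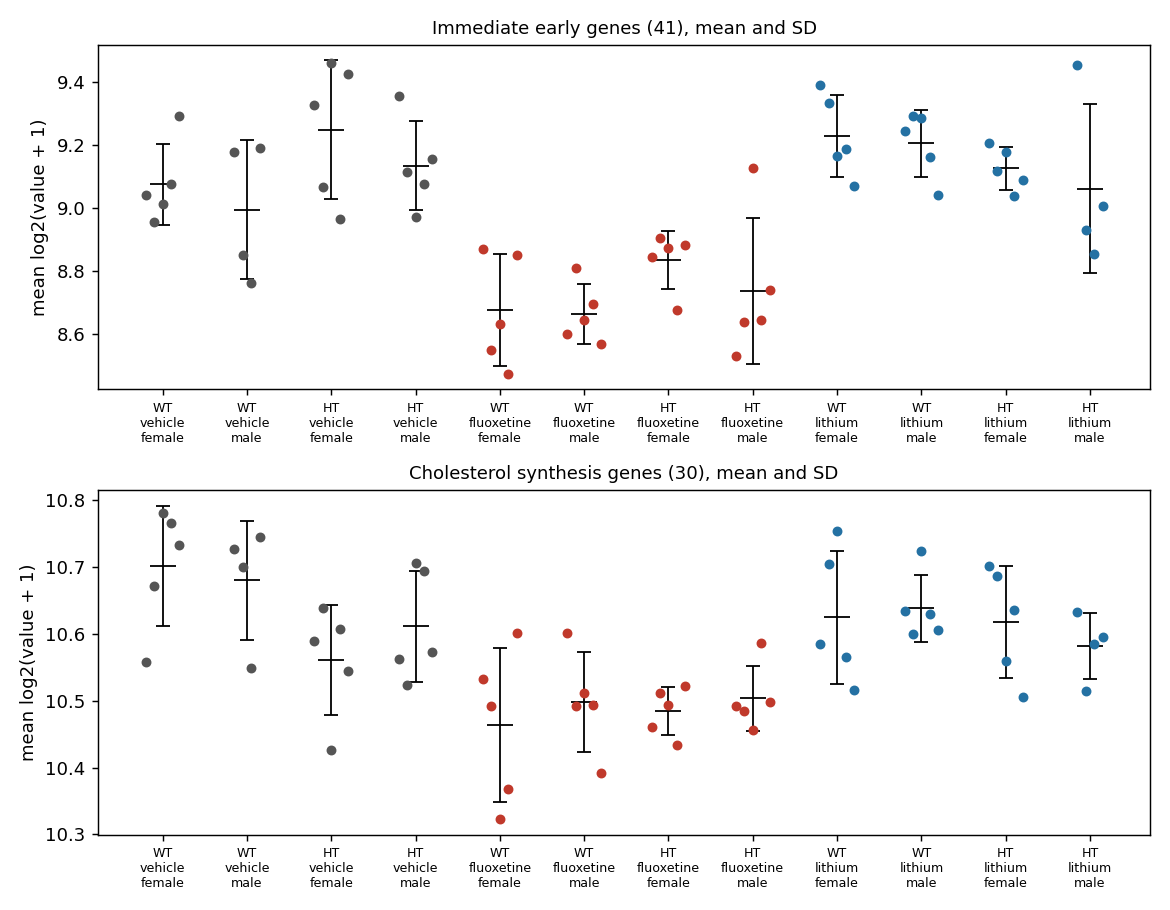
Mean log2(value + 1) of 41 immediate early genes (upper panel) and 30 cholesterol synthesis genes (lower panel) in each library, by group (x axis); points are libraries, and bars show the mean and SD. Both axes are cropped and do not start at 0. All 10 fluoxetine libraries of each genotype lie below the vehicle mean of their genotype and sex in both panels.

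Fluoxetine in HT-labelled mice lowered immediate early genes as well and raised genes of the unfolded protein response. Of the 41 immediate early genes 21 fell and 0 rose, 24 when adjusted over the list alone, with a median of -0.32. Arc fell by 1.70 ± 0.24, from 3831 ± 1250 normalized reads (SD, n = 10) to 1234 ± 621 (n = 10). Nr4a1, Sik1 and Junb, all induced by neuronal activity, fell by 0.95 ± 0.13, 0.89 ± 0.12 and 0.89 ± 0.14. Of 27 unfolded protein response genes 11 rose and 0 fell, 17 when adjusted over the list alone, and the median was 0.13. Hspa5, the main chaperone of the endoplasmic reticulum, rose by 0.35 ± 0.06 (adjusted p = 0.000142), from 6978 ± 713 to 8951 ± 1200 normalized reads, and was higher in 10 of 10 treated mice. Manf, a secreted stress-induced factor, rose by 0.28 ± 0.04, Pdia3 by 0.20 ± 0.03 and Dnajc3 by 0.20 ± 0.04. In females Hspa5, Manf, Pdia3 and Dnajc3 rose by 0.499, 0.373, 0.288 and 0.247, and in males by 0.21, 0.185, 0.115 and 0.156. All of these treated females and none of the males had Gm10221 reads, and the sex interaction passed for none of these genes.

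The lower genes shared several names with those above: Zfp189 fell by 0.96 ± 0.08, Per1 by 0.65 ± 0.06, Stk40 by 0.50 ± 0.05, Nab2 by 0.54 ± 0.06, Zfp366 by 0.69 ± 0.09 and Itpkc by 0.46 ± 0.06. Depp1, a FOXO target, fell by 2.12 ± 0.26, from 72.2 ± 20.9 to 16.0 ± 5.27 normalized reads. Dyrk3, a kinase gene, fell by 0.55 ± 0.07, Arl4d by 0.67 ± 0.09 and Atp8b2, a lipid flippase gene, by 0.23 ± 0.03. Higher genes included Flrt3 (0.41 ± 0.06), the endothelial transcription factor gene Sox18 (0.66 ± 0.10), Foxq1 (0.74 ± 0.11), Klf6 (0.30 ± 0.04), the potassium channel gene Kcnj2 (0.66 ± 0.11) and Smad6 (0.86 ± 0.15), an inhibitor of BMP signalling. Of 30 cholesterol synthesis genes 4 fell (7 when adjusted over the list alone; median -0.09), with Insig1 at -0.24 ± 0.05 and Lss at -0.17 ± 0.04. In the glucocorticoid response list 5 genes fell and 2 rose, 5 and 4 when adjusted over the list alone, with Per1, Ddit4 (-0.64 ± 0.09) and Dusp1 (-0.77 ± 0.14) among the lower. That list's median was 0.08 while its mean was -0.01, and camera did not call it (adjusted p = 0.436). Of 94 nuclear-coded oxidative phosphorylation genes 11 rose, 19 when adjusted over the list alone, Cox5a by 0.23 ± 0.04.

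In HT-labelled mice 635 genes passed for fluoxetine, 261 higher and 374 lower. Immediate early genes and the unfolded protein response held with an estimated correlation (adjusted p = 0.0212 and adjusted p = 0.0121). With Gm10221 reads as a term the immediate early list lost that call (adjusted p = 0.0796 with an estimated correlation, 10 members lower), its mean log2 change going from -0.405 ± 0.073 to -0.353 ± 0.082, a smaller effect with a wider error, and the unfolded protein response stood at adjusted p = 0.0475. Of the 9 other lists called with the preset correlation none held, among them cholesterol synthesis (adjusted p = 0.530 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.731 with an estimated correlation), microglia markers (median 0.11; adjusted p = 0.731 with an estimated correlation), interferon response (median -0.20, but -0.037 without HT vehicle male 1; adjusted p = 0.740 with an estimated correlation) and striatal neuron markers (median 0.27, mean 0.39, and mean 0.24 without HT fluoxetine male 3; adjusted p = 0.740 with an estimated correlation). All 5 HT fluoxetine females had Gm10221 reads: with those reads as a term 184 genes passed, 165 shared with the 635, and in males, none of which had them, 45 passed among the libraries without reads, 44 shared. Leaving out HT vehicle male 5, HT vehicle female 5 or HT fluoxetine male 2 gave 377, 401 and 406 genes.

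Whether the fluoxetine effect differed between genotypes was tested as an interaction. No gene passed by limma, with 1128 at an unadjusted p under 0.05, and DESeq2 called 2 and edgeR 0. Among the genes open to naming, Cbx7 had the smallest p (-0.22 ± 0.05, HT-labelled effect minus WT-labelled effect, limma adjusted p = 0.652). Next came Mpc2, a mitochondrial pyruvate carrier subunit (0.28 ± 0.07), and the immediate early gene Ier5 (0.47 ± 0.12). The smallest limma adjusted p over all genes was 0.232. Cholesterol synthesis had an interaction median of 0.10 and the unfolded protein response one of 0.08, each with adjusted p = 0.420 with an estimated correlation, so neither list was shown to differ between genotypes. Across genes the log2 effects in both genotypes, which share no library, correlated at r = 0.23 (covariance 0.00910), inside the range of -0.40 to 0.36 given by 100 simulations without effect; genes are not independent replicates. Of the genes called in both, 97 were lower in both, where independent lists give 3.42, and 24 were higher in both, where independent lists give 1.22; 0 were called in opposite directions. Fluoxetine-treated mice of both genotypes compared directly gave 0 genes by limma (1114 unadjusted), 2 by DESeq2 and 0 by edgeR, with Mpc2 (0.23 ± 0.05), Egr4 (0.56 ± 0.12) and Cldn5 (0.32 ± 0.07) at the smallest p and none past the threshold.

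In WT-labelled mice members of the lists of nuclear-coded oxidative phosphorylation and of the cytosolic ribosome rose with lithium, but neither list call held with an estimated correlation (adjusted p = 0.336 and adjusted p = 0.679). With trends on transcript length and GC content removed, an alternative chosen after seeing the data, the mean log2 change of the lists went from 0.154 ± 0.039 to 0.084 ± 0.036 and from 0.115 ± 0.044 to 0.043 ± 0.032, the latter with an interval that includes 0. Of 94 nuclear-coded oxidative phosphorylation genes 35 rose and 0 fell, 56 when adjusted over the list alone, with a median of 0.14. Cox5b, a subunit of cytochrome c oxidase, rose by 0.40 ± 0.05 (limma adjusted p = 7.33e-08), from 3621 ± 191 normalized reads (SD, n = 9) to 4754 ± 321 (n = 10), and was higher in 10 of 10 treated mice. The complex I subunit genes Ndufv2 and Ndufc2 rose by 0.34 ± 0.04 and 0.36 ± 0.05, and Cox5a by 0.29 ± 0.04. Mitochondrially coded genes did not share this direction: 4 of 13 fell, mt-Nd4l by 0.82 ± 0.15, mt-Co2 by 0.70 ± 0.18, mt-Nd3 by 0.58 ± 0.16 and mt-Nd6 by 0.41 ± 0.10, and mt-Atp6, named after its value was seen, was the 1 that rose (1.14 ± 0.19), over all genes as over the list alone. That list was not called (camera adjusted p = 0.264, median -0.016), and mt-Co2 and mt-Atp6 follow the Gm10221 reads. Of 84 ribosomal protein genes 24 rose and 1 fell, 35 and 1 when adjusted over the list alone, with a median of 0.12; Rpl13 rose by 0.32 ± 0.04, Rps2 by 0.24 ± 0.04 and Rps26 by 0.32 ± 0.06. Rpl36 rose by 0.36 ± 0.08 but stood at -0.075 once those trends were removed. In the glucocorticoid response list 7 of 22 genes rose and 0 fell, also 7 when adjusted over the list alone, with Fkbp5, a co-chaperone of the glucocorticoid receptor, at 0.64 ± 0.13, Sult1a1 at 0.63 ± 0.13 and Klf9 at 0.17 ± 0.05. Among immediate early genes 6 of 41 rose, 8 when adjusted over the list alone, including Nptx2 (0.35 ± 0.09), Egr4 (0.49 ± 0.13) and Ptgs2 (0.44 ± 0.11).

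Outside these lists Rpl37rt, a retroposed ribosomal gene copy whose reads are hard to tell from its parent's, stood first (0.84 ± 0.09). H1fx, a linker histone gene (0.69 ± 0.08), Mrps24 (0.56 ± 0.06), the transcription factor gene Cebpb (0.90 ± 0.11), Pcsk1n, an inhibitor of prohormone convertase (0.68 ± 0.08), and Scand1 (1.18 ± 0.14) rose. So did Gnptg (0.28 ± 0.03), Wipf3 (0.44 ± 0.05) and Trir (0.49 ± 0.06). Rpl37rt, H1fx, Scand1 and Trir are among the genes that follow the Gm10221 reads (0.64 ± 0.11, 0.40 ± 0.08, 0.95 ± 0.13 and 0.35 ± 0.06 for that term), and among females with those reads lithium minus fluoxetine was 0.11 ± 0.09, 0.11 ± 0.08, 0.07 ± 0.10 and 0.07 ± 0.06, none of which passed. Lower genes were Taf15 (-0.38 ± 0.05), the long noncoding RNA Rian (-0.28 ± 0.04), Mllt6 (-0.21 ± 0.03), Vezt (-0.18 ± 0.03), the zinc transporter gene Slc30a9 (-0.17 ± 0.03) and Atxn1 (-0.25 ± 0.04). Stx16 (-0.17 ± 0.03), Odf2 (-0.23 ± 0.04) and Snapc1 (-0.16 ± 0.03) fell as well, and Srp54b (-0.43 ± 0.07) has near-identical copies that can share its reads. Mllt6, Srp54b and Atxn1 follow the Gm10221 reads too (-0.18 ± 0.04, -0.31 ± 0.08 and -0.20 ± 0.05), with lithium minus fluoxetine at -0.07 ± 0.04, -0.14 ± 0.07 and -0.04 ± 0.03 in those females, none passing. The lists of lithium's known target pathways were not called. Of 27 inositol metabolism genes 2 rose and 1 fell, and in the WNT target list 1 of 24 rose (camera adjusted p = 0.884 and adjusted p = 0.953). Camera did not call the list of mTOR and GSK3 signalling genes either. Over all 17925 genes 1339 passed in these mice, so such counts do not show that these genes moved less than others.

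In HT-labelled mice members of the same lists rose with lithium, and again neither call held with an estimated correlation (adjusted p = 0.788 and adjusted p = 0.898). With length and GC trends removed the mean log2 changes went from 0.153 ± 0.039 to 0.086 ± 0.036 and from 0.094 ± 0.044 to 0.029 ± 0.032. Of the oxidative phosphorylation genes 47 of 94 rose and 0 fell, 54 when adjusted over the list alone (median 0.15), with Ndufv2 up by 0.42 ± 0.04 (adjusted p = 5.12e-09), from 2201 ± 128 normalized reads (SD, n = 10) to 2945 ± 297 (n = 9). Cox5a, Ndufab1, Ndufc2 and Cox5b rose by 0.37 ± 0.04, 0.37 ± 0.05, 0.40 ± 0.05 and 0.37 ± 0.05. Of the ribosomal protein genes 29 rose and 1 fell, 40 and 3 when adjusted over the list alone (median 0.12; Rpl35 0.41 ± 0.05), and without HT lithium female 4 the list's mean went from 0.094 to 0.056. Of 13 mitochondrially coded genes 3 fell, 4 when adjusted over the list alone, mt-Nd6 by 0.48 ± 0.10, mt-Co2 by 0.76 ± 0.18 and mt-Nd4l by 0.72 ± 0.15, while mt-Atp6 (1.26 ± 0.19) and mt-Co3 (0.69 ± 0.24), named after their values were seen, rose; the list was not called (camera adjusted p = 0.771). In the unfolded protein response list 10 of 27 rose, 12 when adjusted over the list alone, Pdia3 by 0.23 ± 0.03, Canx by 0.15 ± 0.04 and Calr by 0.17 ± 0.04. Of 41 immediate early genes 5 fell and 1 rose, over all genes as over the list alone, with Arc at -0.79 ± 0.25 and Nr4a1 at -0.45 ± 0.13. Among endothelial and mural markers 4 of 28 fell, 9 when adjusted over the list alone, including Tek (-0.30 ± 0.09) and Pdgfrb (-0.17 ± 0.05). Over all 17925 genes 2919 passed in these mice, so the counts of the immediate early and endothelial lists lie near the share over all genes.

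Scand1 (1.17 ± 0.14), Fjx1 (0.43 ± 0.05), Basp1, a growth-cone protein (0.34 ± 0.04), and the clathrin light chain gene Clta (0.26 ± 0.03) rose in these mice. Mllt6 (-0.35 ± 0.03) led the lower genes, followed by Ankzf1 (-0.39 ± 0.04), Gramd1a (-0.26 ± 0.03), Pkd1 (-0.23 ± 0.03), Akap8l (-0.46 ± 0.06), Cpne1 (-0.39 ± 0.06), Zfp142 (-0.24 ± 0.04) and Cbx7 (-0.25 ± 0.04). Scand1 and Mllt6 follow the Gm10221 reads, as given above. Of the genes named by smallest p for lithium, only Wipf3 and Slc30a9 passed for lithium minus fluoxetine among females with those reads. Their values were 0.28 ± 0.05 and -0.12 ± 0.03 (limma adjusted p = 0.011 and adjusted p = 0.041). Gramd1a and Pkd1 stood at -0.01 ± 0.03 and -0.01 ± 0.04, and Zfp142 lay the other way (0.03 ± 0.05). With 10 and 8 libraries, a miss there does not show that lithium had no effect. Zfp366 and Atp8b2, both lower with fluoxetine, fell by 0.69 ± 0.10 and 0.21 ± 0.03 with lithium. In those females they lay the other way (0.26 ± 0.12 and 0.09 ± 0.04), a difference that holds the effect of fluoxetine as well. In the list of mTOR and GSK3 signalling genes 7 of 38 fell and 2 rose, 7 and 3 when adjusted over the list alone: the translational repressor gene Eif4ebp2 (-0.18 ± 0.04), Tsc1 (-0.15 ± 0.04) and Tsc2 (-0.10 ± 0.03), which restrain mTOR, and Rps6 (-0.17 ± 0.04). Axin2, a WNT feedback gene, fell by 0.23 ± 0.05, and Lef1, a WNT transcription factor gene, by 0.49 ± 0.13, 2 of 24 in that list. Camera called neither list (adjusted p = 0.259 and adjusted p = 0.331). As 2919 of all 17925 genes passed in these mice, a few members passing does not set a list apart.

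Lithium passed 1339 genes in WT-labelled mice (778 higher, 561 lower) and 2919 in HT-labelled mice (1479 higher, 1440 lower), of which 503 were higher in both and 342 lower in both, where independent lists give 64.2 and 45.1; 1 went in opposite directions. The effects in both genotypes correlated at r = 0.60 across genes (covariance 0.0394), above the highest of 100 simulations without effect, 0.54. Every lithium library of both genotypes and no vehicle library had Gm10221 reads, a division that the simulations leave out. The overlap and the correlation are thus not free of it. Camera called 10 lists in WT-labelled and 5 in HT-labelled mice with the preset correlation, and with an estimated correlation no call remained: besides those above, the unfolded protein response had adjusted p = 0.631 in WT-labelled and adjusted p = 0.788 in HT-labelled mice with an estimated correlation, and glucocorticoid response (adjusted p = 0.134) and immediate early genes (adjusted p = 0.631) were called with the preset value in WT-labelled mice. The endothelial list had adjusted p = 0.898 with an estimated correlation in HT-labelled mice. Striatal neuron markers had a median of 0.39 (2 of 24 rose) and 0.42 (3 of 24 rose, Tac1 0.62 ± 0.16 and Penk 0.67 ± 0.18), much of it from single mice: without WT lithium male 3 and without HT lithium female 2 the medians were 0.189 and 0.230 and camera no longer called the list (adjusted p = 0.0842 and adjusted p = 0.183). All libraries together gave adjusted p = 0.947 and adjusted p = 0.898 with an estimated correlation.

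The 4 other lists called for lithium in WT-labelled mice each had adjusted p = 0.947 with an estimated correlation: interferon response (2 of 31 rose; median 0.14, but 0.075 without WT lithium male 1, which ended the call at adjusted p = 0.129), cholesterol synthesis, and markers of myelinating oligodendrocytes and of astrocytes. Of the cholesterol genes 2 of 30 fell, also 2 when adjusted over the list alone, Idi1 by 0.26 ± 0.06 and Tm7sf2 by 0.17 ± 0.05 (median -0.053). Myelin markers lay lower in 31 of 36 with 0 passing (median -0.17, but -0.256 without WT vehicle male 3), and the call ended without WT vehicle female 5 (adjusted p = 0.0524) or male 2 (adjusted p = 0.155) or WT lithium female 1 (adjusted p = 0.0722), male 1 (adjusted p = 0.0863) or male 4 (adjusted p = 0.0585). Astrocyte markers lay higher in 23 of 30 (median 0.042), of which Apoe, a lipid carrier gene, rose (0.28 ± 0.06), with 3 rising when adjusted over the list alone. That call ended without WT lithium male 2 (adjusted p = 0.121, median 0.008), female 5 (adjusted p = 0.0785) or female 4 (adjusted p = 0.0736), and the median was 0.027 without WT vehicle male 4 and between 0.065 and 0.078 without WT lithium female 3 or male 1 or WT vehicle female 1 or male 3. With Gm10221 reads as a term neither the cholesterol nor the myelin list was called (adjusted p = 0.932 and adjusted p = 0.549, medians -0.0048 and 0.069).

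Every lithium library and no vehicle library had Gm10221 reads, so lithium and vehicle were never compared among libraries alike in that respect. With those reads as a term, which the data identify through the fluoxetine females and which was chosen after seeing the data, 3 genes passed in WT-labelled mice (Ezr, Grasp and Gm17473, singled out after their values were seen) and 0 in HT-labelled mice by limma, where 2768 had an unadjusted p under 0.05; over the genes called without the term the median SE rose from 0.054 to 0.082 in WT-labelled and from 0.053 to 0.080 in HT-labelled mice, and the median absolute effect fell from 0.211 to 0.162 and from 0.205 to 0.152. Both lowered the test statistics. Of these genes 95.6% and 96.6% kept their sign, but they were chosen by the fit without the term on the same libraries. That share therefore does not tell lithium from the division. Among females with Gm10221 reads, 10 lithium against 8 fluoxetine libraries gave 346 genes, 243 higher and 103 lower with lithium, a difference that holds the effect of fluoxetine as well.

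**Figure D4:**
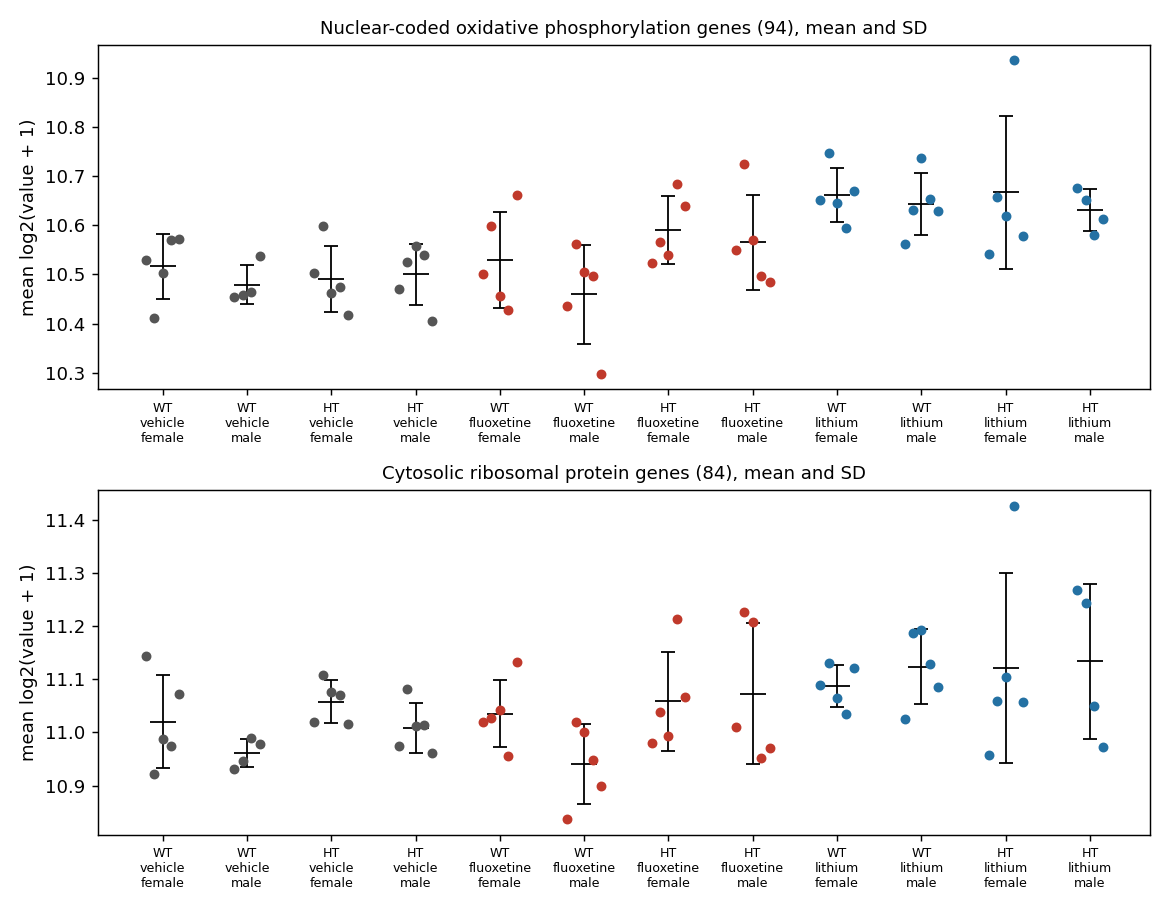
Mean log2(value + 1) of 94 nuclear-coded oxidative phosphorylation genes (upper panel) and 84 cytosolic ribosomal protein genes (lower panel) in each library, by group (x axis); points are libraries, and bars show the mean and SD. Both axes are cropped and do not start at 0. In the upper panel all 10 WT and all 9 HT lithium libraries lie above the vehicle mean of their genotype and sex.

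The lithium effect was not shown to differ between genotypes for any gene. No gene passed the interaction by limma (1196 unadjusted), DESeq2 called 4 and edgeR 0; Cbx7 (-0.25 ± 0.05, adjusted p = 0.193), the phosphatase gene Ptpra (0.14 ± 0.03) and Farp1 (-0.17 ± 0.04) had the smallest p. Immediate early genes had an interaction median of -0.26, 39 of 41 members lying lower, with adjusted p = 0.295 with an estimated correlation. Lithium-treated mice of both genotypes compared directly gave 0 genes by limma (2006 unadjusted, smallest adjusted p = 0.0697), 16 by DESeq2 and 0 by edgeR. Haus2 (0.25 ± 0.05), Spata33 (0.29 ± 0.06) and Slf1 (0.19 ± 0.04) had the smallest p there. Leaving out any 1 of 7 libraries moved this count from 0: to 81 without WT lithium male 1, 40 without HT lithium male 4, 19 without WT lithium female 1, 5 without HT lithium male 1, 2 without HT lithium female 2 or WT lithium male 2, and 1 without WT lithium male 4.

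Whether a drug moved HT-labelled mice toward the WT-labelled state was asked by correlating the vehicle genotype effect with the drug effect in HT-labelled mice. The values were r = -0.46 for fluoxetine and r = -0.27 for lithium across 17925 genes. Shared HT vehicle libraries alone give a mean of -0.47 and -0.46 in simulations without effect. When those libraries were divided so that no library served both sides, r was -0.05 for fluoxetine and -0.00012 for lithium, and the covariance of -0.0158 lay close to the simulated -0.0132 for fluoxetine, as did -0.0123 and -0.0134 for lithium. No reversal was seen beyond the shared controls, but the test could hardly show one. With 0 genes passing for genotype in vehicle, little measured effect was there to reverse. The simulated values also ran widely, from -0.75 to -0.0065 for fluoxetine and from -0.79 to -0.14 for lithium. Whether either drug moves HT-labelled mice toward the WT-labelled state stays undecided.

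The drugs were also compared with each other within a genotype. In HT-labelled mice their effects correlated at r = 0.52 and in WT-labelled mice at r = 0.48, inside the ranges of 0.11 to 0.72 and 0.22 to 0.73 that shared vehicle libraries gave in 100 simulations without effect. The covariances of 0.0278 and 0.0226 also lay inside the simulated ranges, 0.00285 to 0.0330 (mean 0.0132) and 0.00579 to 0.0299 (mean 0.0154). With the vehicle libraries divided r was 0.24 and 0.16. In HT-labelled mice 167 genes were higher with both drugs and 194 lower with both; independent lists give 21.5 and 30.04, values that leave out the shared vehicle libraries. When each drug had vehicle libraries of its own, a test added after seeing the data, an average of 28.6 genes were higher and 26.5 lower with both over 20 divisions, where independent lists give 2.80 and 4.06. All 5 HT fluoxetine females, like every lithium library and no vehicle library, had Gm10221 reads, so this overlap is not free of that division. In WT-labelled mice 23 genes were higher and 16 lower with both, where independent lists give 3.65 and 5.13, and 7 were lower with fluoxetine and higher with lithium; with vehicle libraries of their own, 0.775 were higher and 0.55 lower on average, where independent lists give 0.331 and 0.370, and about as many went in opposite directions as in the same one, so no agreement is shown there. Against the same WT vehicle libraries Idi1 fell with either drug (-0.40 ± 0.06 and -0.26 ± 0.06), and Fkbp5, Sult1a1 and Mertk rose with either. These are examples of genes that went the same way and show no common action of the drugs.

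Sexes were compared within each effect. The sex interaction gave 0 genes by limma for genotype in vehicle (327 unadjusted; DESeq2 1, edgeR 0), fluoxetine in WT-labelled mice (330 unadjusted; DESeq2 1, edgeR 0), lithium in WT-labelled mice (472 unadjusted; DESeq2 1, edgeR 0) and lithium in HT-labelled mice (510 unadjusted; DESeq2 2, edgeR 0). For fluoxetine in HT-labelled mice 2 genes passed, Gm10221 (6.93 ± 1.10, females minus males) and Rpl37rt (0.93 ± 0.18), both among the genes that divide the libraries as above, and DESeq2 called 8 and edgeR 0. Within females alone fluoxetine gave 67 genes in WT-labelled and 447 in HT-labelled mice, and within males alone 18 and 37. Lithium gave 280 and 1228 genes in females and 177 and 536 in males, and genotype in vehicle 0 in either sex by limma (1030 unadjusted in females and 288 in males; DESeq2 3 and 1, edgeR 0). The lower counts in males are not a shown difference between sexes, given the interaction test.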

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

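The tests of the division by Gm10221 reads, both as a pattern and as a source of the other 2, of transcript length and GC content and of the dissection by olfactory bulb markers were chosen only after the result was seen, and the bound for other splits of the libraries was written down after they were seen.

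The libraries fell into 27 with and 31 without reads on the pseudogene Gm10221. An effect of lithium as the whole cause is argued against by 8 libraries outside the lithium arms with such reads, all from fluoxetine females. With the division as a term 98 genes passed (58 higher, 40 lower), among them Gm10221, which defines the division and counts as a pseudogene below. They were spread over 21 chromosomes with at most 8 on any, which argues against a variant that acts only on genes near it. A variant with effects elsewhere in the genome was not tested. Of the 98, 14.3% (exact 95% interval 8.04 to 22.8) were pseudogenes or mitochondrially coded, against 2.11% of other genes (Fisher's exact p = 2.63e-08). In 30 at least 10% of the 31-base sequences lay in transcripts of another gene, 30.6% against 13.1% of other genes (Fisher's exact p = 6.56e-06). Another 30 shared none, a criterion chosen after the first result was seen. Any sharing was found in 69.4%, against 65.3% of other genes. The genes that shared none argue against reads traded between copies as the whole cause and leave their share open. A difference in how or when libraries were made stays open as a candidate explanation, since the labels name no batch. No biological explanation was tested other than the drug and a variant acting on genes near it.

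Oxidative phosphorylation genes lay higher under lithium by 0.15 ± 0.03 in their mean log2 value over both genotypes. The division by Gm10221 reads is argued against as the whole cause: its own term was -0.016 ± 0.043, with an upper bound of 0.07, while lithium stood at 0.17 ± 0.05 beside it, though that term rests on the 8 fluoxetine females with reads. Once trends on transcript length and GC content were removed the effect was 0.085 ± 0.026 (0.03 to 0.14), so a bias of short transcripts may account for part of it and cannot be told apart from the rest. Litter stays open because 0 mice have a litter label and each dam had a single drug. A drug effect on respiratory gene expression is therefore a hypothesis that these libraries leave open.

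Immediate early genes changed under fluoxetine by -0.39 ± 0.05 in their mean log2 value over both genotypes. In males, none of which had Gm10221 reads, the difference was -0.365 (95% interval -0.52 to -0.21), which argues against the library division. With olfactory bulb and striatal markers as covariates it was -0.391 (-0.49 to -0.29), which argues against tissue taken at the edge of the dissection. Litter or handling before tissue collection stays open, as these genes respond to arousal within minutes and 0 mice carry a litter or a collection time in the labels. Reduced activity-dependent transcription under fluoxetine is thus a hypothesis, consistent with the values in both sexes but untested against handling.

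The result that differed between the sexes was the fluoxetine effect in HT-labelled mice, with 2 genes, both of them part of the library division above. Among 132 checks of groups of 4 or 5 mice, 12 found a mouse far from the rest of its group, where chance gives about 6.6. HT vehicle male 1 had 24060000 recovered reads against 28660000 to 30520000 in its group. Tanc2 stood at 7424 normalized reads in HT fluoxetine female 4 (others 8150 to 8424) and at 6961 in WT vehicle male 3 (others 7782 to 7828). For mt-Atp6 WT fluoxetine male 3 had 19100 (others 28460 to 30990). In mean log2 values, HT fluoxetine female 4 had 8.677 for immediate early genes (others 8.845 to 8.904), WT lithium male 3 had 10.72 for cholesterol synthesis (others 10.60 to 10.63), and HT fluoxetine male 2 had 10.26 for the unfolded protein response (others 10.31 to 10.33). WT vehicle male 4 had 10.54 for oxidative phosphorylation, where the others all had 10.46. Striatal neuron markers stood at 9.316 in HT lithium female 2 (others 7.134 to 7.558) and 6.773 in HT vehicle female 1 (others 6.995 to 7.053). Olfactory bulb markers stood at 6.781 in HT lithium female 2 (others 8.165 to 8.683) and 7.724 in HT lithium male 4 (others 8.355 to 8.482).

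Other splits of the same libraries were refitted to see how often they reach the real count, with mice taken as independent. For each main drug effect only 1 of 100 splits, the real one, gave as many genes. Fluoxetine in WT-labelled mice gave 248 against 78 at most elsewhere, and in HT-labelled mice 635 against 85. Lithium gave 1339 against 430 and 2919 against 492. The same holds with 1 of 100 for fluoxetine in WT-labelled males (18 against 3), in HT-labelled females (447 against 2) and males (37 against 4), and for lithium in WT-labelled females (280 against 6) and males (177 against 62) and HT-labelled females (1228 against 718) and males (536 against 212). The highest other splits for lithium still set most lithium libraries, all with Gm10221 reads, against most vehicle libraries. Those reads lay in 2 of 10 against 8 of 9 for WT-labelled mice and 7 of 9 against 2 of 10 for HT-labelled mice. For HT-labelled females and males alone it was 1 of 5 against 4 of 5 and 0 of 4 against 4 of 5. Such counts hold part of the real difference and are not given by chance alone. All splits exchanged single mice within a sex, so they cannot exclude chance differences between litters, which the labels do not name. For lithium, and for fluoxetine in HT-labelled females, the real split was also the division by Gm10221 reads. Those counts therefore do not single out the drug. The sex interaction of fluoxetine in HT-labelled mice (2 genes) was reached by 3 of 100 splits, the highest other giving 16. For fluoxetine in WT-labelled females 7 of 100 splits gave 67 or more and the highest 1537, so chance among single mice is not excluded either. Where the real count was 0, all 100 splits were as large, the highest others giving 1, 972 and 27 for genotype under vehicle, fluoxetine and lithium, 0 and 1 for the interactions of fluoxetine and lithium with genotype, 2, 1416, 330 and 874 for the sex interactions of genotype, fluoxetine in WT-labelled mice and lithium in WT-labelled and HT-labelled mice, and 2 and 1 for genotype in vehicle females and males. Splits with several times the real count point to a structure in the samples: in those with 972, 1416 and 1537 genes the olfactory bulb marker mean, put through the same contrast, came to 1, 2.75 and -1.57 log2 units, against -0.31, 0.42 and 0.33 in the real ones. In those with 330 and 874 genes it came to -0.46 and 0.031, against -0.39 and -0.34, so these markers do not set them apart. Both splits mixed lithium and vehicle libraries: Gm10221 reads lay in 4 of 10 against 6 of 9, and in 2 of 9 against 7 of 10. Such splits keep the difference between lithium and vehicle libraries in the data, so they give no null for a sex interaction. What sets them apart was not tested.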

How the results depend on the processing

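Of the named genes and lists, 6334 values under alternatives kept direction and side of the threshold, 505 fell short of it, 25 newly passed and 3 reversed: Rpl36 under lithium in WT-labelled mice went to -0.075 with length and GC trends removed, and with the Gm10221 term cholesterol synthesis (median from -0.053 to -0.0048; adjusted p = 0.932) and myelin markers (median from -0.169 to 0.069; adjusted p = 0.549) lay the other way by camera in the lithium effect in WT-labelled mice; the cause was not tested. Many of the 6334 values come from refits with a single library left out, which stay close to the main fit. The tally therefore does not measure agreement under any one alternative. With the Gm10221 term almost no gene passed for lithium, as given below. The alternatives with Gm10221 reads, with length and GC trends, with olfactory markers and with edgeR, and the genotype effect over the 3 drug arms, were chosen after seeing the data. Every library had at least 23270000 reads, and no alternative lowered the depth, so what it limits was not tested.

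DESeq2 gave 3 genes for genotype in vehicle, 2 under fluoxetine, 16 under lithium and 1 over the 3 drug arms, where limma gave 0, and 2 and 4 for the fluoxetine and lithium interactions with genotype. For the sex interactions it gave 1 for genotype, 1 and 8 for fluoxetine in WT-labelled and HT-labelled mice, and 1 and 2 for lithium. Within a sex it gave 3 and 1 for genotype in females and males, 144 and 34 for fluoxetine in WT-labelled females and males, and 291 for lithium in WT-labelled males. For fluoxetine in HT-labelled mice the sex interaction went from 2 genes to 0 with edgeR, 5 with quantile normalization and 1 with the replicate block. Fluoxetine in WT-labelled mice gave 158 genes from only the groups compared. With 2 surrogate variables fluoxetine in HT-labelled mice gave 975 genes, lithium in WT-labelled mice 2215 and the lithium interaction 2. With fewer mice the drug counts fell: females only, 67 for fluoxetine in WT-labelled mice and 280 and 1228 for lithium, while genotype under lithium rose from 0 to 3; males only, 18 and 37 for fluoxetine and 177 and 536 for lithium. With the Gm10221 term genotype under lithium gave 9 genes, fluoxetine 129 and 184, and lithium 3 and 0, with wider errors, since that term and lithium nearly coincide, and with smaller effects (medians of the called genes from 0.211 to 0.162 and from 0.205 to 0.152). Libraries without those reads gave 146 for fluoxetine in WT-labelled and 45 in HT-labelled mice. With length and GC trends removed genotype under lithium gave 1, and the oxidative phosphorylation mean under lithium fell from 0.154 to 0.085. Apart from fewer samples for the lower drug counts and the wider errors, the cause of these moves was not tested.

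The preset correlation gave 10, 11 and 11 lists by camera for genotype under vehicle, fluoxetine and lithium. It gave 12 and 6 for the fluoxetine and lithium interactions with genotype. With an estimated correlation no list was called for genotype in any arm (0, 0 and 0), for lithium (0 and 0) or for the interactions (0 and 0), and 2 lists were called for fluoxetine in each genotype. Fry gave 0 for genotype in each arm and both interactions, 2 for fluoxetine in each genotype and 4 for lithium in each genotype. With control libraries divided, the correlations for reversal went to -0.054 for fluoxetine and -0.00012 for lithium, and those between drugs to 0.163 in WT-labelled and 0.243 in HT-labelled mice.

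Leaving out each library in turn gave 159 to 373 genes for fluoxetine in WT-labelled mice, 377 to 687 in HT-labelled mice, 934 to 1313 for lithium in WT-labelled and 2216 to 2961 in HT-labelled mice. Genotype gave 0 under vehicle, 0 to 2 under fluoxetine (2 without WT fluoxetine female 2) and 0 to 81 under lithium (81 without WT lithium male 1, 40 without HT lithium male 4). Both interactions with genotype stayed at 0. The sex interactions gave 0 to 1 for genotype, 0 to 2 and 1 to 5 for fluoxetine in WT-labelled and HT-labelled mice and 0 for lithium in both.

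Replicate numbers recur across groups, but same-numbered libraries did not deviate together (mean correlation -0.00017), and 13 of 58 libraries correlated best with one of their own number, so the numbers do not pair mice. The replicate block moved no other count by over 1.5 times.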

Other observations

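The comparison of lithium with fluoxetine among females with Gm10221 reads and the lists with a library left out were chosen only after the result was seen. In the interferon response list 2 of 31 genes rose with lithium in WT-labelled mice and 3 in HT-labelled mice. B2m rose by 0.19 ± 0.05 and 0.27 ± 0.05 and H2-D1 by 0.30 ± 0.07 and 0.26 ± 0.07, while H2-K1 in HT-labelled mice stood at 0.195 ± 0.085 (adjusted p = 0.112) and was higher in 5 of 9 treated mice. When adjusted over the list alone 2 rose in each genotype. Camera called that list in WT-labelled mice, with adjusted p = 0.947 with an estimated correlation, and not without WT lithium male 1 (adjusted p = 0.129, median from 0.139 to 0.075). Of 99 autism risk genes 7 fell and 2 rose with lithium in WT-labelled mice, among them Nlgn3 (-0.27 ± 0.06), Taok1 (-0.14 ± 0.04) and Tnrc6b (-0.18 ± 0.05), and 14 fell and 6 rose in HT-labelled mice, with Tnrc6b at -0.24 ± 0.05 and the histone methyltransferase gene Kmt2a at -0.26 ± 0.06. Adjusted over the list alone the counts were 8 and 4, and 15 and 8, and camera did not call the list (adjusted p = 0.0814 and adjusted p = 0.259). Over all 17925 genes 1339 passed with lithium in WT-labelled and 2919 in HT-labelled mice. The counts of the autism and interferon lists do not stand far above that share. Nlgn3 is among the genes that follow the Gm10221 reads. Under fluoxetine in HT-labelled mice 3 of 28 endothelial and mural markers rose, also 3 when adjusted over the list alone: the lipid transporter gene Mfsd2a (0.23 ± 0.06), the VEGF receptor gene Kdr (0.34 ± 0.09) and Abcc9 (0.34 ± 0.09).

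Among females with Gm10221 reads, where lithium and fluoxetine can be compared on like libraries, 23 of 41 immediate early genes were higher with lithium and 0 lower (median 0.44), as were 8 of 30 cholesterol synthesis genes (median 0.18). The comparison does not say which drug moved. Oxidative phosphorylation genes differed there by 0.12 in their mean log2 value (0.02 to 0.23), with 1 of 94 passing. Of the genes it called, 70 were called in the same direction for lithium in WT-labelled and 68 in HT-labelled mice, where independent lists give 13.8 and 28.3; the comparisons share lithium libraries, which raises such counts by itself.

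Olfactory bulb markers varied more within groups than between them. Their mean log2 value ran from 5.90 to 8.99 within HT fluoxetine males alone, and group means lay between 7.17 and 8.24. WT fluoxetine female 3 was the highest of all at 9.38.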
